A study of Arabidopsis thaliana with 6 samples.

How the data were processed

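Expression was measured in 6 samples of microdissected root meristems of Arabidopsis thaliana, 3 of wild type and 3 of 35S:miR396 plants, on an Affymetrix array. Per the labels' protocols, total RNA was extracted with a kit that keeps small RNAs and labelled with biotin by a kit that starts from the 3' end of transcripts. The authors deposited log2 values per probe set that were made with GCRMA, per the submitters' processing notes. GCRMA corrects the background by probe sequence, normalizes between arrays and summarises the probes of a set. Its version was not given in the sources used here, and the arrays' scanner files were not used here. That the values are on a log2 scale, not centred per gene, was read from the values themselves: they run from 2.25 to 14.3, and the median of each array lies between 3.88 and 3.99. GCRMA pulls dim probe sets to a floor, so folds against a level near the floor are lower bounds. The floor need not be the same for all probe sets: nad7 repeated a value of 2.41 in most arrays, and PDF1.2 repeated 4.79. Called probe sets with a group mean below 3 were counted as near the floor, and there were 31. Probe sets with a higher floor are not among them and could pass the filter. Normalization between arrays sets them to a common scale, so a change in total RNA per cell could not be seen.

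Groups and replicate numbers were taken from the sample titles. The table held 22810 probe sets. Control probe sets (64) were left out, and a probe set was tested if its log2 value was at least 4 in at least 3 of the 6 arrays, whatever their group, which left 11364. R 4.3.3 and limma 3.58.1 were used. Each probe set was fitted with lmFit, with 1 coefficient for 35S:miR396 minus wild type and no replicate block, and eBayes with a variance prior that follows the mean level. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, and a probe set was called at an adjusted p under 0.05. Errors of log2 fold changes are limma's moderated standard errors (SE); errors of levels are standard deviations over 3 arrays (SD). The fit was tested on simulated arrays with the real means and spreads of the 11364 probe sets, of which 200 were changed by known folds. It recovered 49.1% of 57 probe sets changed 1.5-fold, 86.3% of 73 changed 2-fold and 97.1% of 70 changed 4-fold, with 4.22% false calls. The simulated noise was independent between probe sets, and 200 were changed where 2838 were called in the real arrays. These shares check the fit and do not give the power or the false calls in the real arrays.

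Probe sets were named only from the platform annotation given for this table. It gave 1 gene for 13513 probe sets, several genes for 503 and did not list 8794, which are unnamed here. Of those with 1 gene, 11933 have only a locus code as their symbol and 1580 a symbol of their own, and 13436 were matched by gene identifier to a locus of a gene table of assembly TAIR10.1. Of the tested probe sets 6229 had 1 gene, 240 several and 4895 were unnamed, and of the 2838 called ones 1274 were unnamed. No gene was named from a probe set with several genes, except that a list gene with no probe set of its own could be represented by one. Coordinates are not given.

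Gene lists (23), the test, the filter, the alternatives and the rule for named genes were fixed before the data were examined. Only 57 of the 396 list entries (14.4%) had a named probe set and 31 were tested, so 4 of these lists had the 3 tested members needed for a test. For that reason 17 further lists were drawn from the genes that the annotation names. They were chosen after the values had been opened and after a first look at the genes with the highest and lowest fold changes, so their tests describe these data and are not independent evidence. 1 entry was then removed from the endoplasmic reticulum list because its locus does not encode the protein that its symbol was taken for. A list gene took the probe set with the highest mean over the 6 arrays. The 21 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with the Benjamini-Hochberg adjustment over the 21 lists. camera with a correlation estimated per list, and fry, which tests whether a list's genes move on balance in 1 direction, were run beside it. With preset correlation 7 lists were called, and none of them was called with an estimated correlation. The estimate was 0.0036 for the endoplasmic reticulum list, below the preset 0.01, yet its unadjusted camera p rose from 0.00267 to 0.0358. A higher correlation therefore does not explain the loss of that call. In the other called lists the estimates ran from 0.045 to 0.69.

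Named genes were the tested members of the GRF, GIF and PLETHORA lists; the 12 highest and 12 lowest log2 fold changes among called probe sets with 1 gene, a symbol and no overlap of the groups; and up to 4 called members of each other list by absolute log2 fold change, or, where none was called, the member with the smallest p. The second part was read in both ways, with locus codes counted as symbols and without them. This gave 105 genes, 97 of them called, and 64 kept the call when each array was left out in turn. A few further members of the lists are named beside them, chosen after their values were seen, and were fitted without each array too.

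The 3' to 5' difference was taken from 6 pairs of control probe sets and compared with an exact permutation test over the 10 splits of the arrays. Alternatives were no filter, a mean log2 value of at least 6, no trend and a robust variance prior, a further quantile normalization, centring each array on its median, 16 added on the linear scale, array weights, the replicate number as a block, leaving out each array, leaving out probe sets of several genes, 1 probe set per gene, other thresholds and other list tests. No filter together with no trend was added after seeing the data. Figures were drawn from the same values.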

Results

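Transcript levels were measured in microdissected root meristems of Arabidopsis thaliana seedlings at 7 days after sowing. Wild-type plants (3 arrays) were compared with plants carrying 35S:miR396 (3 arrays), in which a strong constitutive viral promoter drives the microRNA miR396. The labels call the 3 samples of each group biological replicates and do not say how their plants were grown apart, so the p-values measure the spread between these samples. Each array gave a log2 GCRMA value for 22810 probe sets, of which 64 were controls. About 35% of the other probe sets lay within 0.1 of the lowest value in each array, from 35.1% to 35.4%. A total of 11364 probe sets reached a log2 value of 4 in at least 3 of the 6 arrays and were tested. The number of arrays limits the precision of every value below.

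The comparison asks which transcripts differ in the root meristem when miR396 is overexpressed. Of the 11364 probe sets, 2838 passed limma's test at an adjusted p under 0.05, which is 25% of those tested. Of these, 1438 were higher and 1400 lower in 35S:miR396, with a median absolute log2 fold change of 0.54. A change of at least 2-fold was found at 476 of them, 335 higher and 141 lower. The counts of called members given below for each list are to be read against the share of 25%. The highest fold belonged to AT4G38410, a dehydrin gene, at 30.8-fold (log2 fold change 4.94 ± 0.56, SE), and the largest fall, 21.0-fold, was at a probe set that the annotation used here does not name. The 2 groups of 3 values did not overlap at 2833 of the called probe sets and at 45.7% of all tested ones, where chance gives 10%. The count fell to 941 with no filter on dim probe sets. Of the 97 called genes that the naming rule picks, 58 lost the call there, and 67 with no trend as well, AT4G38410 among them. It lay between 1052 and 1606 when any array but replicate 2 of 35S:miR396 was left out. In order, those fits left out replicate 1 (1298), 2 (1052) or 3 (1499) of wild type, or replicate 1 (1606) or 3 (1362) of 35S:miR396.

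The first principal component held 70.4% of the variance and separated the groups. Its scores were -22.9, -24.6 and -28.9 in wild type and 37.9, 11.3 and 27.2 in replicates 1, 2 and 3 of 35S:miR396, so that replicate 2 lay nearest to wild type. Pearson correlations across tested probe sets, which are not independent replicates, were 0.988 to 0.993 within wild type and 0.978 to 0.990 within 35S:miR396. Between the groups they were 0.944 to 0.976. Without replicate 2 of 35S:miR396, 3813 probe sets were called, 1942 higher and 1871 lower.

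**Figure D1:**
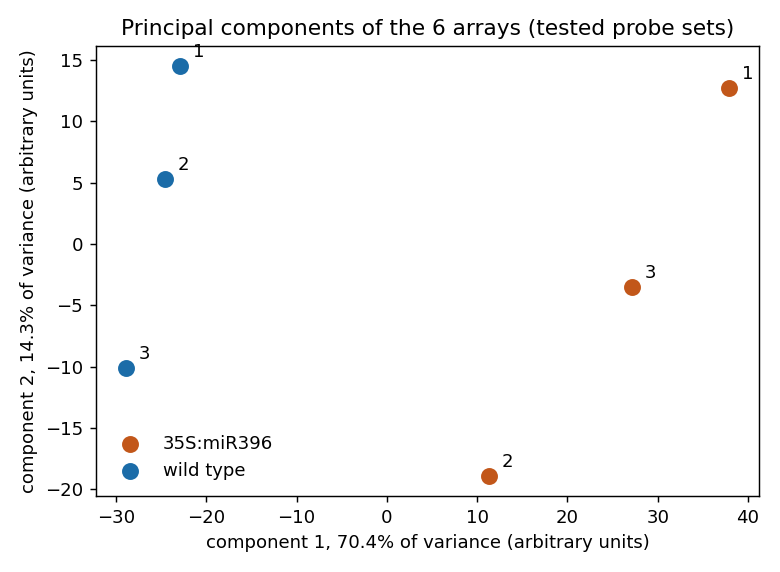
Scores of the 6 arrays on principal components 1 and 2 (arbitrary units; 70.4% and 14.3% of the variance), computed from the tested probe sets; each point is 1 array, coloured by group and marked with its replicate number. All 3 wild-type arrays lie at or below -22.9 on component 1, and the 35S:miR396 arrays lie at 11.3, 27.2 and 37.9.

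Growth-regulating factor (GRF) genes are the main known targets of miR396 and would check the labels. None of the 7 targeted GRF genes, and none of the other GRF genes, GIF cofactors and BHLH74 on a list of 6, had a probe set that the annotation used here names. Their levels were not analysed here, and the genotype rests on the labels alone.

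BBM, an AP2-domain factor of the PLETHORA family that maintains the root stem cell niche, was 2.83-fold higher in 35S:miR396. Its log2 value was 5.58 ± 0.08 (SD, n = 3) in wild type and 7.08 ± 0.25 (SD, n = 3) in 35S:miR396 (adjusted p = 0.00122 by limma). It was the only tested member of the PLETHORA and AIL list. Adjustment over the list alone therefore leaves its p unchanged and adds no evidence to the test over all probe sets, which it passed. Among 14 root meristem regulators, a list made after the values had been opened, 6 rose, BBM again among them, none fell and 8 did not pass the test. CLE41, the precursor of a peptide that promotes division of vascular stem cells, rose by 1.78 ± 0.16 (log2, SE) from a wild-type level near the floor (2.53), so its fold is a lower bound. ULT1, a SAND-domain regulator of meristem activity, rose by 1.24 ± 0.09 (SE). UPB1, a bHLH factor that represses peroxidase genes where cells leave the meristem, rose by 1.08 ± 0.22 (SE), and AGL42, a MADS-box gene active in the quiescent centre, rose by 0.68 ± 0.14 (SE). The call of UPB1 was lost without replicate 3 of 35S:miR396 (1.09, adjusted p = 0.0518; at most 0.11 over the alternatives). UPB1 and AGL42 also lost the call with no filter on dim probe sets. PHV, a class III homeodomain gene restricted by another microRNA, rose by 0.58 ± 0.11 (SE). The list's median log2 fold change was 0.25 (camera, adjusted p = 0.0191). With an estimated correlation the adjusted p was 0.501, the highest of its alternatives, which started at 0.00482. It was 0.094 without replicate 2 of 35S:miR396 (median 0.30), 0.0839 with array weights (median 0.37), and 0.228 over members with a mean log2 value of at least 6, whose median was -0.00623.

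Few of the planned genes of cell division could be tested, 6 of 34 in the G2 and mitosis list and 3 of 33 in the S-phase and DNA replication list. In the G2 and mitosis list the median log2 fold change was -0.03 (camera, adjusted p = 0.618), from -0.0948 without replicate 2 of 35S:miR396 to 0.00531 without replicate 3. AUR1, an Aurora kinase of mitosis, passed the test at -0.29 ± 0.09 (SE, adjusted p = 0.0491), and no member passed when adjusted over the list alone. That call was lost without any single array other than replicate 2 of 35S:miR396, without which 2 members fell, with values of -0.32, -0.30 and -0.25 without replicates 1, 2 and 3 of wild type. Without replicates 1 and 3 of 35S:miR396, each left out alone, its value was -0.26, and its adjusted p was at most 0.139 over the alternatives. The call was also lost with no filter on dim probe sets, no trend, a further quantile normalization, median centring and the replicate block. The 3 tested members of the S-phase and DNA replication list had a median of -0.01 and a mean of 0.02 (adjusted p = 0.855). The median ran from -0.0977 without wild-type replicate 1 to 0.0556 without replicate 1 of 35S:miR396, and none passed either over all probe sets or adjusted over the list alone. PSF2, a subunit of the replication complex GINS, had the smallest p of the 3, at 0.18 ± 0.11 (SE). TSO1, the only tested member of the G1 cyclin and cell cycle factor list, stood at -0.14 ± 0.08 (SE, adjusted p = 0.215). SIM, a CDK inhibitor that promotes endoreduplication, was the only tested member of the CDK inhibitor and endocycle list. It fell by 0.89 on the log2 scale, from 8.29 ± 0.13 to 7.40 ± 0.27 (SD, n = 3; adjusted p = 0.0079). Adjustment over the list alone leaves the p of an only member unchanged and adds no evidence. The adjusted p of SIM over all probe sets was 0.0585 with no filter on dim probe sets and at most 0.0741 over the alternatives.

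Larger lists of division genes were made after the values had been opened. Of 25 mitosis and division genes, AUR3 rose, AUR1 fell and 23 did not pass the test (median -0.04, camera adjusted p = 0.756). This share of calls is below the 25% of all tested probe sets, a difference that was not tested. That median ran from -0.0541 without replicate 2 of 35S:miR396 to 0.0297 without wild-type replicate 1. AUR3 stood at 0.76 ± 0.19 (SE, adjusted p = 0.0277), and its call was lost without replicate 2 (0.81) or 3 (0.58) of wild type and without replicate 1 (0.70) or 3 (0.70) of 35S:miR396. Of 16 replication and chromatin assembly genes, 5 fell, none rose and 11 did not pass (median -0.10, but -0.0617 without wild-type replicate 3; adjusted p = 0.173). The list passed with no filter on dim probe sets (adjusted p = 0.0356) and over all probe sets on the array (0.039), where dim probe sets join the genes it is compared with. Over the alternatives the adjusted p reached 0.763, with an estimated correlation. The members that fell were 4 genes of histone H2B and HON4, a linker-histone-like protein. HTB1 fell by 0.67, HTB11 fell by 0.56, HTB2 fell by 0.48 and HTB4 fell by 0.25 on the log2 scale. HON4 stood at -0.33 ± 0.08 (SE), and its call was lost without replicate 2 (-0.33) or 3 (-0.29) of wild type and without replicate 1 (-0.32) or 3 (-0.32) of 35S:miR396. Of 15 tubulins and microtubule organisers, 3 fell and 2 rose (median -0.07, but -0.0426 without wild-type replicate 3; adjusted p = 0.612). The 3 that fell were beta-tubulin genes: TUB5 fell by 0.77, TUB6 fell by 0.38 and TUB1 fell by 0.97. The 2 that rose were TRM28 (1.22 ± 0.24, SE) and TRM19 (0.66 ± 0.16, SE). The call of TUB1 was lost without each wild-type array (-0.98, -1.02 and -0.90 without replicates 1, 2 and 3) and without replicate 3 of 35S:miR396 (-1.03). That of TRM19 was lost without replicate 1 (0.53) or 2 (0.71) of wild type and without replicate 3 of 35S:miR396 (0.59). Without replicate 2 of 35S:miR396, 4 mitosis and division genes fell. With no filter AUR1, AUR3, HTB2, HON4, TUB1, TUB5, TRM28 and TRM19 lost the call, and HTB1 and HTB11 with no trend as well.

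Most tested genes of the responses to cold, drought and abscisic acid were higher in 35S:miR396. Of 11 tested members of this list, made after the values had been opened, 8 rose, none fell and 3 did not pass the test. EEL, a bZIP factor of abscisic acid signalling, rose 6.28-fold, from 5.24 ± 0.10 to 7.89 ± 0.24 (SD, n = 3; adjusted p = 0.000212). COR27, a cold-regulated gene, rose by 2.19 ± 0.30 (log2, SE), DI19, a drought-induced zinc-finger gene, by 1.54 ± 0.25, and TIL, a temperature-induced lipocalin, by 1.49 ± 0.23. The dehydrin COR47 rose by 0.85 ± 0.11 (SE). The dehydrin LTI30 stood at 1.02 ± 0.27 (SE), and its call was lost without each wild-type array (1.16, 1.12 and 0.78 without replicates 1, 2 and 3) and without replicate 1 (0.78) or 3 (1.11) of 35S:miR396. The list's median was 0.90 (camera, adjusted p = 3.52e-05). With an estimated correlation the adjusted p was 0.501, and over the other alternatives it was at most 0.00543. The median level of the list was 7.61 in replicate 2 of 35S:miR396, against 8.17 and 8.03 in replicates 1 and 3 and at most 7.15 in wild type. With no filter on dim probe sets 3 members were called, and DI19, TIL and LTI30 lost the call, as COR27 did with no trend as well.

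Among 9 autophagy genes, a list made after the values had been opened, 3 rose, none fell and 6 did not pass the test. Of the 9, 8 encode ATG8 proteins, which coat the forming autophagosome, and the 3 that rose are among them. ATG8B rose 8.92-fold, from 4.16 ± 0.31 to 7.32 ± 0.42 (SD, n = 3; adjusted p = 0.000729). ATG8G rose by 0.88 ± 0.13 (log2, SE) and ATG8D by 0.73 ± 0.16. The call of ATG8D was lost without each wild-type array (0.71, 0.77 and 0.72 without replicates 1, 2 and 3) and without replicate 3 of 35S:miR396 (0.76). It was lost with no filter on dim probe sets too, and that of ATG8G with no trend as well. Without replicate 2 of 35S:miR396, 6 members were called. The list's median was 0.40 (camera, adjusted p = 0.0119), and it ran from 0.28 without replicate 1 of 35S:miR396 to 0.63 without replicate 2. The adjusted p was 0.750 with an estimated correlation and 0.230 over members with a mean log2 value of at least 6, and the lowest over the alternatives was 0.00198.

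Some genes of ribosome biogenesis were higher in 35S:miR396. Of 7 tested members of this list, 4 rose, none fell and 3 did not pass the test, and 4 rose when adjusted over the list alone. PES, BOP1 and WDR12 encode the partners of a complex that matures the large ribosomal subunit. PES rose by 0.58 ± 0.07 (log2, SE), BOP1 by 0.37 ± 0.09 and WDR12 by 0.36 ± 0.09. DIM1A, an rRNA dimethylase, rose by 0.61 ± 0.11 (SE). The list's median was 0.36 (camera, adjusted p = 0.0191), and the adjusted p was 0.501 with an estimated correlation and at most 0.0483 over the other alternatives. Without replicate 1 of wild type 2 members were called, without replicate 2 of wild type 1, and without replicate 1 of 35S:miR396 2. The call of DIM1A was lost without wild-type replicate 2 (0.60). The call of BOP1 was lost without each wild-type array (0.39, 0.38 and 0.34 without replicates 1, 2 and 3) and without replicate 1 of 35S:miR396 (0.30). WDR12 lost it without replicate 1 (0.28) or 2 (0.36) of wild type and without replicate 1 (0.36) or 3 (0.37) of 35S:miR396. With no filter on dim probe sets 1 member, PES, was called. A further list of 10 RNA polymerase I and III and pre-rRNA processing genes was made after the values had been opened. This list had 4 members that rose, DIM1A again among them, and 6 that did not pass (median 0.12, adjusted p = 0.0753). It passed without replicate 3 of wild type (adjusted p = 0.0471) or of 35S:miR396 (0.041), with no filter on dim probe sets (0.0114), over members with a mean log2 value of at least 6 (0.0239), over all probe sets on the array (0.0125) and by fry (0.0268). With an estimated correlation the adjusted p was 0.748, the highest of its alternatives. Of its members, PRH75, a nucleolar RNA helicase, rose by 0.98 ± 0.10 (SE) and IMP4, a factor of early rRNA processing, by 0.44 ± 0.07. DIM1B stood at 0.32 ± 0.09 (SE), and its call was lost without any single array, at values from 0.29 without replicate 3 of 35S:miR396 to 0.38 without wild-type replicate 2. It was also lost with no filter, a further quantile normalization, median centring and the replicate block. Without replicate 2 of wild type, 2 of its members were called. The array's control probe set for 25S rRNA went from 11.41 ± 0.06 in wild type to 12.17 ± 0.14 in 35S:miR396 (SD, n = 3). The control for 5S rRNA, a product of RNA polymerase III, went the other way, from 4.34 ± 0.39 to 3.92 ± 0.62, and its groups overlapped. Neither control was tested. The labelling starts from the 3' end of transcripts, and how it takes up rRNA was not measured here, so these signals need not follow rRNA levels.

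Genes of protein folding in the endoplasmic reticulum were lower. Of 13 tested members of this list, made after the values had been opened, 6 fell, none rose and 7 did not pass the test. CRT1b, a calreticulin, fell by 0.39 on the log2 scale, from 12.02 ± 0.02 to 11.63 ± 0.08 (SD, n = 3; adjusted p = 0.0033). DER1, a derlin of the degradation pathway for misfolded proteins, fell by 0.53. The J-domain cochaperones ATERDJ2B and ATERDJ3B fell by 0.59 and fell by 0.42. BZIP60 and BZIP28, factors that switch on the response to unfolded proteins, did not pass the test, at -0.21 and -0.18. The list's median was -0.21 (camera, adjusted p = 0.014), and the adjusted p was 0.501 with an estimated correlation and at most 0.0458 over the other alternatives. With no filter on dim probe sets 3 members were called, and ATERDJ3B lost the call, as ATERDJ2B did with no trend as well.

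**Figure D2:**
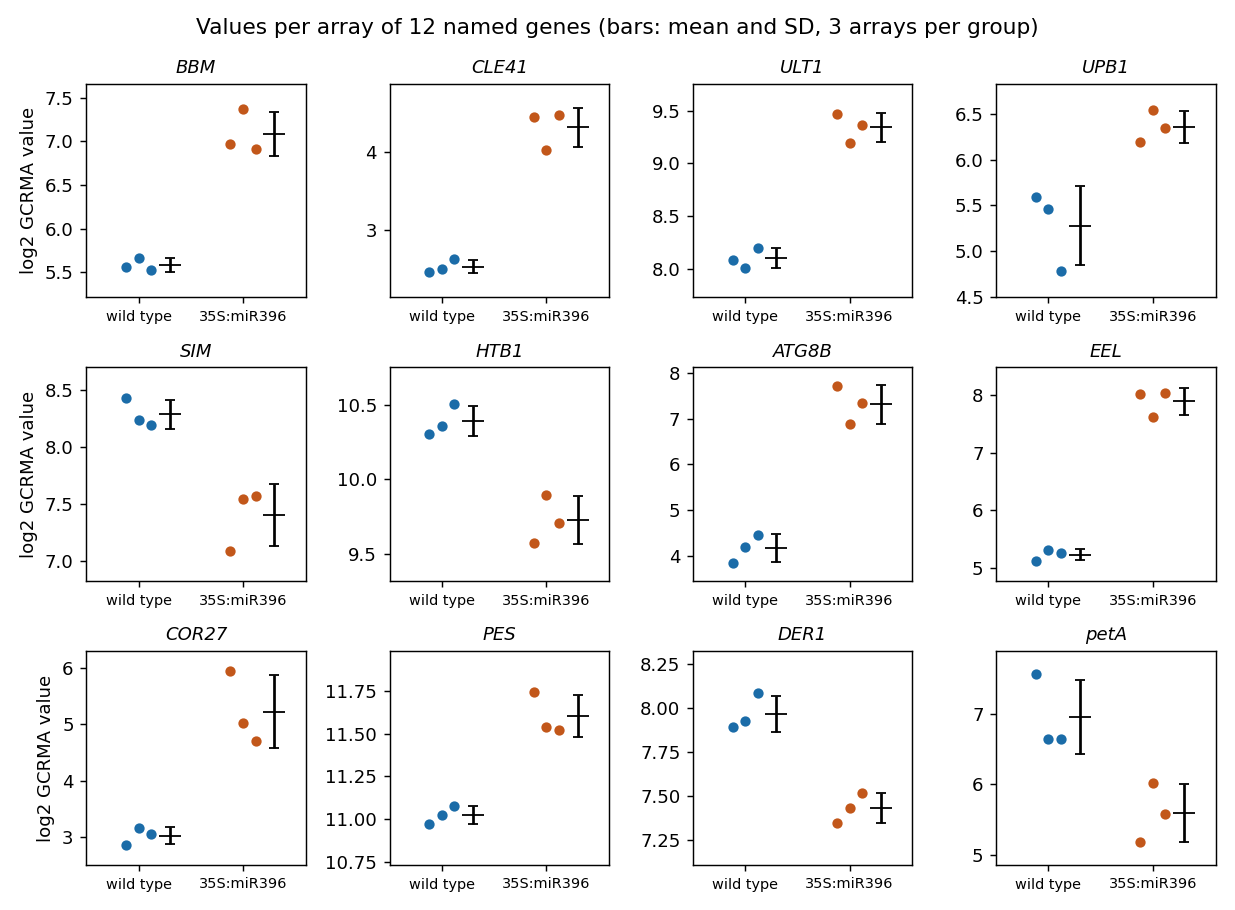
Log2 GCRMA values of 12 genes named in the report, with 1 point per array (3 wild type, 3 35S:miR396) and the group mean with its SD beside them; the vertical axes do not start at 0 and differ between panels. The groups do not overlap for any of the genes, with BBM at 5.58 and 7.08 and ATG8B at 4.16 and 7.32 on average.

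Most tested transcripts encoded in the plastid genome had lower values in 35S:miR396, but the list tests disagreed on a shift of the group. Of 57 tested members of this list, made after the values had been opened, 16 fell, none rose and 41 did not pass the test, and 54 had a negative log2 fold change. The median was -0.48 (camera, adjusted p = 2.11e-06), while the adjusted p was 0.763 with an estimated correlation and 0.154 by fry. petA and psaI, of the cytochrome complex and photosystem I, fell by 1.36 and fell by 1.28 on the log2 scale (adjusted p = 0.0199 and 0.0202). The call of petA was lost without replicate 1 (-1.16) or 3 (-1.36) of 35S:miR396. cemA, of the plastid envelope, stood at -1.31 ± 0.39 (SE), and its call was lost without replicate 1 (-1.02) or 2 (-1.31) of wild type and without replicate 1 (-1.13) or 3 (-1.12) of 35S:miR396. The call of psaI was lost without replicate 2 of wild type (-1.36) and without replicate 1 (-1.29) or 3 (-1.10) of 35S:miR396. Wild-type replicate 1 stood above the others: the median level of the list was 7.37 in it, 6.95 and 6.64 in wild-type replicates 2 and 3, and 6.64, 6.63 and 6.35 in 35S:miR396. Without wild-type replicate 1 the median log2 fold change was -0.30 and 3 members were called. Without replicate 2 of wild type 3 were called, and without replicates 1, 2 and 3 of 35S:miR396 the counts were 1, 28 and 0. With no filter on dim probe sets no member was called, and cemA lost the call with no trend or a robust prior too.

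Cell wall genes went both ways. In the planned list of wall loosening and primary wall genes, 1 of 5 tested members rose and 4 did not pass, with 1 adjusted over the list alone (median 0.28, camera adjusted p = 0.756). The median ran from 0.0158 without replicate 3 of 35S:miR396 to 0.48 without wild-type replicate 3. The called member, the expansin EXPA15, stood at 0.39 ± 0.11 (SE, adjusted p = 0.038), and its call was lost without replicate 1 (0.35) or 2 (0.33) of wild type and without replicate 2 (0.32) or 3 (0.38) of 35S:miR396. In a list of 13 expansins and xyloglucan endotransglucosylases made after the values had been opened, 3 rose, EXPA15 again among them, and 1 fell (median 0.28, adjusted p = 0.674). Without 1 array this median was always lower, from 0.0158 without replicate 3 of 35S:miR396 to 0.19 without wild-type replicate 1. EXPA20 rose by 1.61 ± 0.29 (log2, SE). XTH21 stood at 1.61 ± 0.40 and XTH16 at -1.39 ± 0.36 (SE). The call of XTH21 was lost without each array other than wild-type replicate 3, at values from 1.21 without wild-type replicate 2 to 1.74 without replicate 3 of 35S:miR396. That of XTH16 was lost without each array other than replicate 2 of 35S:miR396, at values from -1.45 without wild-type replicate 2 to -1.02 without replicate 1 of 35S:miR396. All 4 genes lost the call with no filter on dim probe sets, EXPA20 with an adjusted p of at most 0.0988 over the alternatives, and EXPA15 lost it with no trend too.

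Both tested targets of other microRNAs were higher over all probe sets. They passed adjusted over the list alone too, but with 2 members that test is milder and adds no evidence. APS4, an ATP sulfurylase, rose by 0.96 ± 0.17 (log2, SE, adjusted p = 0.0108), and PHV is given above. The call of APS4 was lost with no filter on dim probe sets, and its adjusted p was at most 0.0886 over the alternatives. Markers of other cell types had few named probe sets. JKD, of the stem cell niche list, stood at -0.07 ± 0.17 (SE), the xylan synthase gene IRX10 of the xylem list at 0.22 ± 0.12 and the polygalacturonase gene RCPG of the root cap list at 0.65 ± 0.47. The call of RCPG was gained without replicate 2 of 35S:miR396 (1.15). The auxin-responsive gene GH3.5 stood at 0.29 ± 0.14 (SE). The defensin gene PDF1.2 had the same value, 4.79, in 5 of the 6 arrays, so it carries no information on a difference. Each of these 5 was the only tested member of its list, and none passed the test. The lists of auxin synthesis and transport, cytokinin response, root hair, phloem, endodermis, photosynthesis, heat shock and touch and wounding genes had no tested member.

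The highest log2 fold changes among called, named probe sets whose groups did not overlap belonged to AT4G38410, AT1G20070, AT3G23880, AT1G33790, ATG8B, AT4G19980, AT3G10020, AT2G25450, AT5G19875, CML43, EEL and AT4G35720, from 4.94 to 2.58. Wild type lay near the floor for AT3G23880 and AT1G33790, so their folds are lower bounds. Of their wild-type levels, that of AT4G38410 varied most, at 6.77 ± 1.24, against 11.71 ± 0.36 in 35S:miR396 (SD, n = 3). The calls of AT3G10020 and AT2G25450 were lost without replicate 2 (3.02 and 2.60) or 3 (2.54 and 2.59) of wild type and without replicate 3 of 35S:miR396 (3.09 and 2.94). Among genes with a symbol other than a locus code, the highest also held SIS, SBT1.3, COR27, LPR1, LEP, UGT76C2, SGP1, CLE41 and LCR68. In wild type SIS (3.11) and COR27 (3.03) lay just above the limit of 3, so their folds may be lower bounds too. Their lowest log2 fold changes over the alternatives were 1.43 and 1.16. LPR1, a multicopper oxidase of the root's response to low phosphate, rose by 2.18 ± 0.21 (SE), and SBT1.3, a subtilisin-like protease, by 2.22 ± 0.23. LEP, an AP2-domain factor, rose by 2.12 ± 0.20 (SE). UGT76C2, which glucosylates cytokinins, rose 3.79-fold, from 3.83 ± 0.06 to 5.75 ± 0.08 (SD, n = 3; adjusted p = 0.000214). The call of SIS (2.46 ± 0.52, SE) was lost without each wild-type array (2.56, 2.40 and 2.42 without replicates 1, 2 and 3) and without replicate 3 of 35S:miR396 (2.21). AT3G23880, AT3G10020, AT2G25450, CML43, SIS and LCR68 lost the call with no filter on dim probe sets, and AT4G38410 and COR27 with no trend as well.

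Among called, named probe sets without overlap of the groups, the lowest log2 fold changes belonged to AT4G11190, AT1G66800, AT1G73780, AT1G09750, AT5G09570, AT2G42320, AT5G62330, AT2G30890, AT3G03680, AT5G66590, AT3G43960 and AT3G43110, from -3.07 to -2.08. AT2G30890 and AT3G43110 lay near the floor in 35S:miR396, so their falls are lower bounds too. AT1G73780 (3.00) and AT2G42320 (3.03) lay just above the limit of 3 there, so their falls may also be lower bounds. Over the alternatives, their smallest falls on the log2 scale were -1.63 and -1.12. AT5G66590, a gene of the family of secreted PR-1-like proteins, fell from 9.56 ± 0.18 to 7.47 ± 0.37 (SD, n = 3; adjusted p = 0.0011). The call of AT4G11190, a dirigent-like gene, was lost without replicate 1 (-3.06) or 3 (-2.70) of wild type and without replicate 3 of 35S:miR396 (-2.72). Among genes with a symbol other than a locus code, the lowest were ATGSTF13, scpl46, XTH16, petA, psaI, ASPGB1, MSRB9, atpA, HAT2, rps2, OCT5 and TBL25. ATGSTF13, a glutathione S-transferase, fell by 1.53 on the log2 scale. MSRB9, a methionine sulfoxide reductase, fell by 1.14, and HAT2, an auxin-induced homeodomain gene, fell by 1.08. atpA, rps2 and OCT5 each lost the call without replicate 1 (-1.02, -0.93 and -0.76) or 3 (-1.11, -1.004 and -0.98) of 35S:miR396 and without replicate 2 (-1.33, -1.26 and -1.20) or 3 (-1.32, -1.19 and -0.95) of wild type. rps2 and OCT5 also lost it without wild-type replicate 1 (-0.77 and -0.95) and with the replicate block, and OCT5 and atpA with no trend. Of all these, only AT1G73780, AT2G42320, AT2G30890, AT5G66590, AT3G43110, ATGSTF13 and MSRB9 kept the call with no filter on dim probe sets, ATGSTF13 and MSRB9 not with no trend as well.

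**Figure D3:**
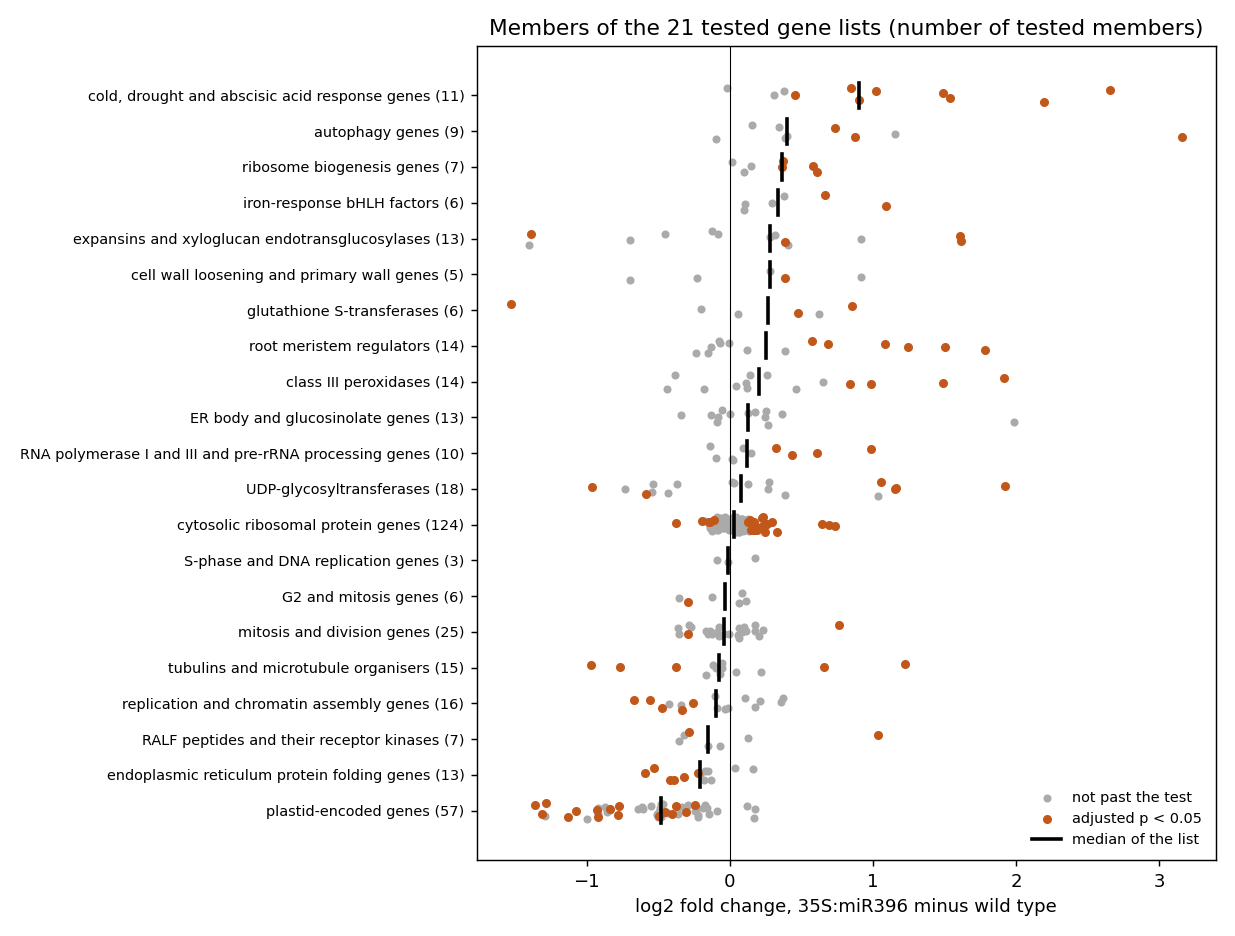
Log2 fold change (35S:miR396 minus wild type, horizontal axis) of each tested member of the 21 gene lists with at least 3 tested members, 1 point per gene, with the number of members after each list's name and a bar at the list's median. Coloured points passed limma's test at an adjusted p under 0.05; the cold, drought and abscisic acid list has the highest median (0.90) and the plastid-encoded genes the lowest (-0.48).

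RNA quality was read from the array's control transcripts of actin, GAPDH and ubiquitin. The difference between their 3' and 5' probe sets, averaged over 6 pairs, was 1.32 ± 0.10 in wild type and 1.36 ± 0.13 in 35S:miR396 (log2, SD, n = 3). The groups differed by 0.03 (exact permutation test, two-sided, p = 0.9), in a design whose smallest p is 0.1.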

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

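The tests of a wrong label and of the plastid and cold lists themselves were chosen only after the result was seen, as was the demand that a value pass its bound by more than its spread.

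Signals outside the comparisons appeared in 2 of the 7 plant control probe sets that are not part of the 3' to 5' pairs: all 3 arrays of 35S:miR396 lay above all 3 of wild type. The groups did not overlap, in 1 direction or the other, at 45.7% of all tested probe sets, so this count alone does not stand out. Of the 7, U12639 lay at the floor (2.25) in every array and could not differ. The control for 25S rRNA was higher by 0.76 on the log2 scale, at 11.41 ± 0.06 in wild type and 12.17 ± 0.14 in 35S:miR396 (SD, n = 3). The middle probe set of ubiquitin was higher by 0.50, at 9.93 ± 0.15 and 10.43 ± 0.20. These values carry no test over all probe sets, and how the labelling takes up rRNA was not measured here.

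The groups differed at 2838 probe sets, and 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many. The highest other split gave 0 by limma, with 34 to 742 probe sets at an unadjusted p under 0.05 against 4596 in the real split. Each other split puts arrays of both genotypes in each of its groups, so the difference between genotypes adds to the spread within groups. The counts of these splits are therefore not a measure of what chance gives, and no conclusion is drawn from them. With 10 splits no share under 0.05 can be reached.

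The first pattern is that most plastid-encoded transcripts had lower values in 35S:miR396, with a median log2 fold change of -0.48 over 57 members. A different yield of organelle RNA, which has no long poly(A) tails, could give this, and mitochondrial transcripts would then fall too. Their median was -0.0278 over only 4 tested members, and cox1 among them stood at -1.31 (adjusted p = 0.0536), so this cannot be told apart from a change in the plastids. A single array may also set the shift, through its organelle yield or otherwise. All 4 mitochondrial transcripts peaked in wild-type replicate 1 (median level 6.84, against 5.59 to 6.02 in the others), as the plastid median did. Some bacterial control probe sets, which do not measure organelle RNA, peaked there too, as DapX-5 did (7.98, against 6.66 to 7.22 in the others). Others, such as BioC-3, did not. Without that array the plastid shift was -0.30, of 6 that ran from -0.59 to -0.30, a spread too wide to exclude that 1 array sets it. A lower level of plastid transcripts in the transgenic meristems stays open, untested.

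The second pattern is that replicate 2 of 35S:miR396 lay nearest to wild type. A wrong label is argued against, since it correlated better with each other 35S:miR396 array (0.978 and 0.987) than with any wild-type array (at most 0.976), a difference of mean correlations of 0.00823. Wild-type material in that sample would need 1 share for all genes. The median share of wild-type signal that replicate 2 needs was 0.50 over 505 genes higher and 0.25 over 199 genes lower in the other 2 replicates, a difference of -0.25, where the same difference was 0.09 and -0.09 in replicates 1 and 3. The reference for replicates 1 and 3 includes replicate 2 itself, so their values measure the spread only roughly. The difference of -0.25 passes the limit of 0.2 set for it by less than this spread. A mixed sample and a weaker response of those plants therefore cannot be told apart.

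The third pattern is that most tested cold, drought and abscisic acid genes were higher in 35S:miR396. A single array as the cause is argued against, since the lowest median of the list without 1 array was 0.78 (without replicate 1 of 35S:miR396) against 0.90 with all. Wounding or touch at collection could raise such genes, and rapid wounding and touch genes would then rise too. Their median was 0.13 over 4 tested members, with PUB23 called at 1.05 and PUB22, CML38 and WRKY6 at 0.26, 0.00 and -0.00, so few members and their spread leave this open. Overexpression of miR396 itself stays open, untested against growth conditions of the plates.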

How the results depend on the processing

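No filter together with no trend was the only alternative chosen after seeing the data. The counts of called, higher and lower probe sets stayed within 1.5 times with no trend, a robust prior, quantile normalization, median centring, 16 added, no probe sets of several genes, 1 probe set per gene and the replicate block; calls ranged from 2541 to 2861 there. With no filter they were 941, 464 and 477, and with no trend as well 624, 317 and 307. These fits test 22746 probe sets, and limma's prior degrees of freedom fall from 3.2 to 0.73 and 0.40. Of the 2838 calls, 839 were kept with no filter. A mean log2 value of at least 6 left 958 higher, from fewer probe sets (7134). Array weights gave 4749, 2339 and 2410. The weights were 2.50 for replicate 2 of wild type and 2.50 for replicate 3 of 35S:miR396, against 0.40 to 1.01 for the other arrays. That fit leaned on 1 array per group, and whether this raised the counts was not tested. An adjusted p under 0.10 gave 2125 lower, and a 2-fold limit left 476, 335 and 141, by construction. Without 1 array the counts ranged from 1052 to 3813 called, 583 to 1942 higher and 469 to 1871 lower, and no call shared with the full fit changed sign. Whether equal replicate numbers share a batch is not given by the labels and was not settled here. The deviations of same-numbered samples correlated at 0.40, -0.09 and 0.14. Many bacterial control probe sets were lowest in replicate 3 of both groups. For r2-Bs-lys-M, replicates 1, 2 and 3 stood at 6.26, 5.90 and 5.42 in wild type and 6.11, 5.99 and 5.34 in 35S:miR396. With the replicate block 2844 were called, 1527 higher and 1317 lower, and 2471 of the calls were shared.

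Levels of the miR396-targeted GRF genes were not analysed here. BBM, which stands for the PLETHORA and AIL list, moved by more than its error with 16 added (1.25), with array weights (1.36), with AT1G72570, at the floor, counted as a member (list median 0.75) and without replicate 2 of 35S:miR396 (1.36); it reached 1.58 without replicate 3 and moved by less than its error without each array other than replicate 2. The G2 and mitosis median changed sign over members with a mean of at least 6 (0.0609) and ranged from -0.0948 to 0.00531 without 1 array. The S-phase list had too few members at that mean; its median ranged from -0.0977 to 0.0556 without 1 array, positive without replicates 2 (0.03) and 3 (0.03) of wild type and replicate 1 of 35S:miR396 (0.0556). Neither list passed its test in any alternative. Other medians that changed sign were those of the root meristem regulators (-0.00623) and of expansins and xyloglucan endotransglucosylases (-0.0844) over members with a mean of at least 6, of ribosomal proteins with quantile normalization (-0.00268), of the added mitosis list without wild-type replicate 1 (0.0297) or replicate 1 of 35S:miR396 (0.0269; lowest -0.0541 without replicate 2), and of UDP-glycosyltransferases without replicate 3 of 35S:miR396 (-0.0270; highest 0.175 without wild-type replicate 1). JKD, not called, was positive without wild-type replicate 1 (0.0415) or replicate 1 of 35S:miR396 (0.0159; lowest -0.212 without replicate 2). The cause was not tested for these.

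Over the named genes and their alternatives, 1472 results stayed on their side of the test, 262 lost the call, 3 gained it and 2 changed sign. With no filter 58 of the 97 named calls were lost, and 67 with no trend as well. All 7 list calls ended with an estimated correlation, those of the autophagy, iron and plastid lists ended with fry, and that of the root meristem regulators ended with array weights (0.0839). With no filter the replication and chromatin, RNA polymerase and ribosomal protein lists gained a call. The 3' to 5' difference was -0.11 for GAPDH, 0.14 for ubiquitin, -0.0859 for the second actin pair and 0.21 for the second ubiquitin pair, each alone, against 0.03; without 1 array it ranged from -0.04 to 0.09. Signal over background limits the rest: about 35% of probe sets lie within 0.1 of the lowest value in each array. No difference can be seen for a probe set at the floor in both groups.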

Other observations

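The tests of the gene lists in this part were chosen only after the result was seen, since the lists were made after the values had been opened, and the test of gene order was not.

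Enzymes that conjugate small molecules went both ways. Of 18 UDP-glycosyltransferases, 4 rose, 2 fell and 12 did not pass limma's test, with a median of 0.08 (camera, adjusted p = 0.558; fry, adjusted p = 0.0268). The median ran from -0.0270 without replicate 3 of 35S:miR396 to 0.18 without wild-type replicate 1. Besides UGT76C2 (1.92), the members that rose were UGT87A2 (1.16 ± 0.13, log2, SE), UGT76B1 (1.15 ± 0.29) and UGT73B4 (1.05 ± 0.19), and UGT71C1 fell by 0.97. The calls of UGT76B1 and UGT73B4 were lost without wild-type replicate 2 (0.93 and 0.99), that of UGT76B1 also without wild-type replicate 3 (1.08) and replicates 1 (1.08) and 3 (1.01) of 35S:miR396, and 2 members were then called higher without wild-type replicate 2. Without replicate 2 of 35S:miR396, 4 members fell, and without replicate 3, 1 did. Of 6 glutathione S-transferases, GSTU22 (0.86) and GSTU26 (0.47) rose and ATGSTF13 fell by 1.53 (median 0.27, but 0.14 without replicate 2 of 35S:miR396; adjusted p = 0.674). The call of GSTU22 was lost without replicates 1, 2 and 3 of wild type (0.98, 0.69 and 0.90) and replicates 1 and 3 of 35S:miR396 (0.68 and 0.82). Of 14 class III peroxidases, secreted enzymes that make or use hydrogen peroxide in the wall, 4 rose, none fell and 10 did not pass (median 0.20, adjusted p = 0.162), led by AT5G17820 at 1.91 ± 0.35 (SE). That median ran from 0.13 without wild-type replicate 1 to 0.41 without replicate 1 of 35S:miR396. AT3G21770 (1.49) and AT2G43480 (0.99) lost the call without replicate 3 of 35S:miR396 (1.46 and 0.89), and AT3G21770 also without replicate 1 (1.501). The probe set given to AT4G37520, which other genes share (0.84), lost it with no trend, without replicates 2 (0.66) and 3 (0.80) of wild type and replicates 1 (0.79) and 3 (0.71) of 35S:miR396. Their count was 2 without replicate 1 and 1 without replicate 3 of 35S:miR396. UGT76B1, UGT73B4, GSTU22, GSTU26 and all 4 peroxidases lost the call with no filter on dim probe sets, and UGT71C1 and ATGSTF13 with no trend as well.

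Of 124 cytosolic ribosomal protein genes, 20 rose, 5 fell and 99 did not pass (median 0.03, but -0.00268 with a further quantile normalization; camera adjusted p = 0.149). The list passed with no filter on dim probe sets (adjusted p = 0.00482), also with no trend (0.00482), and over all probe sets on the array (0.0066), and reached 0.851 with an estimated correlation. AT5G39850 (0.74), AT3G13580 (0.69) and AT2G40010 (0.64) rose furthest, and AT4G30800 fell by 0.38. Leaving out replicate 1, 2 or 3 of wild type left 10, 6 or 12 that rose, with 2, 1 and 1 that fell; leaving out replicate 1 or 3 of 35S:miR396 left 12 that rose, with 2 and 1 that fell. Of 6 iron-response bHLH factors, 2 rose, bHLH121 (1.09 ± 0.27, log2, SE) and bHLH104 (0.67 ± 0.16), and all 6 had positive values (median 0.33, adjusted p = 0.0402). With an estimated correlation the adjusted p was 0.763. It was 0.0728 without wild-type replicate 2, and 0.0626 and 0.0789 without replicates 1 and 3 of 35S:miR396. No member was called without wild-type replicate 1, 2 or 3 or replicate 3 of 35S:miR396, and 1 was called without replicate 1 of 35S:miR396. Of 7 RALF peptide and receptor genes, RALFL32 rose by 1.03 ± 0.18 (SE) and RALFL31 fell by 0.28 (median -0.15, adjusted p = 0.674). The median ran from -0.31 without replicate 2 of 35S:miR396 to -0.00651 without replicate 1. The call of RALFL31 was lost without replicates 1, 2 and 3 of wild type (-0.29, -0.26 and -0.30) and replicates 1 and 3 of 35S:miR396 (-0.26 and -0.28), and 2 members fell without replicate 2. It was also lost with the replicate block. RALFL32, bHLH121, bHLH104 and AT4G30800 lost the call with no filter on dim probe sets, and AT5G39850 with no trend as well. None of 13 ER body and glucosinolate genes passed limma's test (median 0.12, adjusted p = 0.558), and the median ran from 0.0304 without wild-type replicate 3 to 0.21 without wild-type replicate 1. BGLU16 had the smallest p, at -0.34 ± 0.13 (SE), and it was called without wild-type replicate 3 (-0.47).

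A chromosome segment that differs between the lines, for example around an inserted transgene, could make called genes cluster. Over 6129 tested genes placed in order, the fullest window of 20 neighbours held 13 of the 1478 called ones, and 0.225 of 10000 shuffled orders reached as many, which argues against a segment with many changed genes but not against 1 with few. Pairs of neighbours that were both called numbered 321, against a mean of 355.7 in shuffled orders. A share of 0.992 of the shuffled orders held as many or more, so such pairs were fewer than in most of them. The cause was not tested.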
